A study of Mus musculus with 8 samples.

How the data were processed

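The series holds 8 RNA-seq libraries from the brain and neural tube of mouse embryos at E11.5, with 2 replicates for each of 2 genotypes (WT and Lin28a and Lin28b double knockout) and each of 2 RNA fractions (total and polysomal). Per the labels' protocols, RNA was isolated with Trizol and strand-specific libraries were made with a NEBNext Ultra Directional kit. FastQC, TopHat and HTSeq and the builds GRCm38, mm10 and mm9 are named in the submitters' processing notes, with no versions, roles or order. The strand setting of the counting, the annotation, the handling of reads that map to several places and the way polysomes were collected are not given in the sources used here. The authors deposited 2 tables of whole-number read counts per gene symbol, not normalized, with 1 column per library and none left over. The series text speaks of 3 groups, while the sample labels give 4, and the labels were followed.

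Among the symbols of total RNA, 5815 are at 0 in every library, while the polysomal table holds far fewer symbols. A few symbols had been turned into dates by a spreadsheet before deposit. The 4 total RNA rows that could not be told apart for this reason were kept in the total RNA fit and left out of joins, so that 5802 genes were shared. Symbols were matched to GENCODE M21 (GRCm38) for transcript length and GC content, which gave a match for 98.4% of the total RNA rows and a GC value for 99.4% of the polysomal rows. Because the builds in the notes have no stated role, coordinates are those of GENCODE on GRCm38 and are used only to place genes.

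Column totals of the total RNA table were 15650360 and 15060560 counts in WT and 15768767 and 15612883 in dKO. In the polysomal table the listed genes summed to 14874143 and 15414712 counts in WT and to 3740980 and 5164982 in dKO, which are sums over part of each library and not its depth. The biological coefficient of variation between replicates was 0.0504 in total RNA and 0.0898 in polysomal RNA.

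Replicates were compared by a chi-square statistic on their counts. Its value per degree of freedom was 3.23 for WT and 2.90 for dKO total RNA, and 2.90 for WT and 25 for dKO polysomal RNA, so no pair differed by so little that it could be a single library deposited under both numbers. The dKO polysomal replicates thus differed most.

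Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each genotype comparison used the 4 libraries of its own fraction. The WT comparison of polysomal with total RNA and the interaction of genotype with fraction used all 8 libraries with 4 group means. Standard errors were computed as the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes. For polysomal RNA these rest on the sums over listed genes, since no library totals were used here. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested members (29 lists in total RNA and 23 in the other comparisons), beside camera with an estimated correlation and fry. Camera with an estimated correlation takes its p-values on the few residual degrees of freedom of the fit. A call lost there thus does not show that correlation between genes undid it. Of 30 lists, that of mitochondrially encoded genes had no row. The lists cover let-7 targets, protein synthesis, growth and cell cycle, stress responses, neural progenitors and neurons, patterning, metabolism, noncoding RNAs, sex-linked genes and markers of other tissues.

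The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined. By that rule Lin28a and Lin28b come first, then in each genotype comparison and in the interaction the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the libraries of the genotypes (5 each for the WT comparison), up to 4 members of each list, and Xist and Ddx3y as a check of the libraries. Predicted genes and pseudogenes were left out of the largest changes; this removed 1 fall in total RNA, 1 rise and 1 fall in polysomal RNA and 2 rises and 1 fall in the interaction. Not every gene the rule allows is printed, and those printed for the lists were picked from them after their values were seen.

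The alternatives chosen beforehand were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a mean of at least 5 CPM, the replicate number as a block, a log2 fold change of at least 1, each library left out in turn and all 8 libraries in 1 fit. Added after the data were seen were an adjustment for transcript GC content and 1 for transcript length (a loess curve with span 0.5 of each library's deviation from the WT mean of its fraction, used as an offset, with none for genes without a GC value, such as Rn45s), a scaling that puts the empty middle of the polysomal ratios at 0, fits without Rn45s, Lars2 and Mir6236, and, for the polysomal lists, Fisher's exact test of the share of members higher against the other listed genes.

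The tests were checked on simulated counts drawn from the real means, with 200 genes changed by known folds. For the total RNA comparison (14594 genes) 69.7% of genes changed 1.5-fold, 84.8% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 3.49% of the calls were false. For polysomal RNA (5777 genes) the shares were 76.1%, 95.5% and 100%, with 2.69% false. For the WT comparison (5780 genes) they were 83.6%, 97.0% and 100%, with 6.50% false, and for the interaction (5780 genes) 59.7%, 95.5% and 98.5%, with 5.62% false. A list of 40 genes shifted by 0.4 on the log2 scale was found in each case, and none of 20 unshifted lists was called. Each gene was drawn independently, with the same trend of spread for all libraries and most genes unchanged. The simulation thus cannot show how often lists of correlated genes are falsely called. Nor does it match the polysomal data, where nearly every gene was called and the dKO replicates differed most. A floor of 3 counts per library, used for the bound on a fold where a group had none, covers counting error only.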

Results

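Total RNA and polysomal RNA, the RNA that co-sediments with several ribosomes at once, were sequenced from the brain and neural tube of mouse embryos at E11.5. The embryos were wildtype (WT) or carried knockout alleles of both Lin28 genes, Lin28a and Lin28b (double knockout, dKO). Lin28a and Lin28b encode RNA-binding proteins that block the maturation of the let-7 family of microRNAs and also bind many messenger RNAs. The series title places the study on the part Lin28 plays in protein synthesis and in the upkeep of neural progenitor cells. The 8 libraries formed 4 groups of 2, namely WT total RNA, dKO total RNA, WT polysomal RNA and dKO polysomal RNA. The labels do not say whether the replicates came from separate embryos or litters, so p-values measure only the spread between these samples, which may be technical. The total RNA table covered the transcriptome, and 14594 of its genes had enough counts to be tested. The polysomal table listed far fewer genes, 5802 of them shared with the total RNA table, and their counts summed to much less in the dKO than in the WT libraries. These polysomal sums cover the listed genes only and are not the depth of the libraries.

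Both targeted genes were lower in every dKO library than in every WT library. Lin28a lies on the minus strand of chromosome 4 from 134003330 to 134018841, and Lin28b on the minus strand of chromosome 10 from 45376620 to 45486395, in the GENCODE annotation of GRCm38. In total RNA, Lin28a fell from 72.8 ± 0.789 to 7.14 ± 0.833 CPM (counts scaled to library size; mean ± SD, n = 2 per genotype), a log2 fold change of -3.35 ± 0.12 (SE; adjusted p = 9.18e-168, edgeR quasi-likelihood test). Lin28b counts were 2014 and 1852 in WT and 755 and 855 in dKO, a log2 fold change of -1.28 ± 0.07 (adjusted p = 1.85e-74). In polysomal RNA the log2 fold changes were -2.69 ± 0.15 for Lin28a and -2.06 ± 0.16 for Lin28b. Counts per gene do not show which exons the remaining reads came from.

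**Figure D1:**
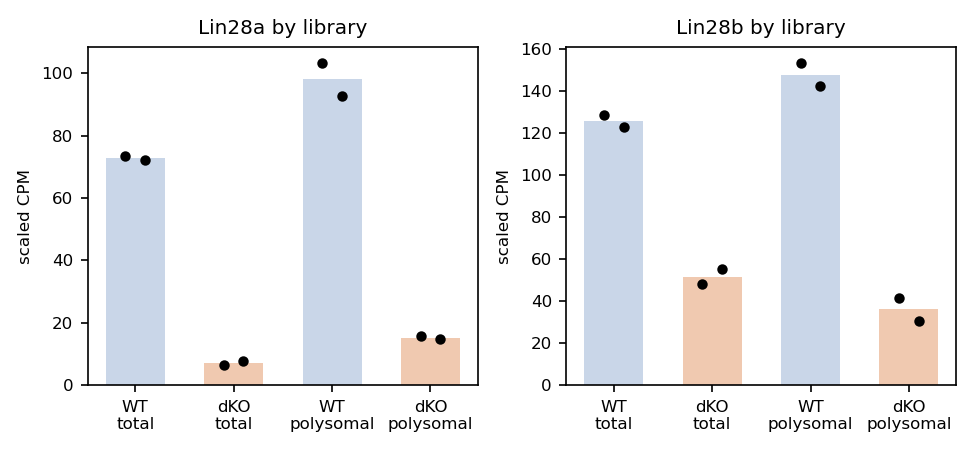
Scaled CPM of Lin28a (left) and Lin28b (right) in each group, with points for the 2 libraries and bars for their mean. Both dKO libraries lie below both WT libraries in each assay, with Lin28a at 6.55 and 7.73 CPM in dKO total RNA against 73.3 and 72.2 in WT.

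The first comparison asked which transcripts differed in abundance between dKO and WT tissue. In total RNA, transcripts of let-7 target genes, of ribosome biogenesis, of DNA replication and of glycolysis were lower in dKO, while transcripts of several Hox genes and of cytoplasmic ribosomal proteins were higher. These are calls by camera at a preset correlation between genes. None of the 12 lists called in total RNA passed with an estimated correlation (adjusted p from 0.148 to 0.301). That estimate lay above the preset 0.01 for glycolysis genes alone (0.0879), and was -0.024 for let-7 targets. For the other lists the loss thus came without a higher correlation, in a setting with few degrees of freedom. Hmga2, a chromatin protein of embryonic progenitors and a classical let-7 target, fell 3.05-fold. Neurod2 and Neurod6, transcription factors of differentiating neurons, rose 7.28-fold and 6.95-fold from low WT levels of 2.24 and 1.60 CPM. Of 14594 genes tested, 4485 passed an adjusted p of 0.05, with 2152 higher and 2333 lower in dKO. Most of these differences were small: the median absolute log2 fold change of the called genes was 0.34, and 133 higher and 93 lower genes also changed by at least 1 on the log2 scale. DESeq2 called 2944 genes, and a fit over all 8 libraries, which tests only genes in both tables and takes in the wider spread of the polysomal libraries, called 1286.

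Beyond Neurod2 (log2 fold change 2.86 ± 0.22) and Neurod6 (2.80 ± 0.27), the 10 largest rises by the rule for named genes included Rgs5, a regulator of G-protein signalling (1.99 ± 0.26), Hsd3b6, a steroid dehydrogenase (1.96 ± 0.13), and Akr1e1, an aldo-keto reductase (1.91 ± 0.14). Ttr, the thyroid hormone carrier made by the choroid plexus, rose by 1.79 ± 0.13 and Slc17a8, a vesicular glutamate transporter, by 1.55 ± 0.19. Nfix, a nuclear factor I transcription factor, rose from 15.1 ± 1.84 to 41.0 ± 1.09 CPM, and the ubiquitin ligase adaptor gene Fbxo44 rose by 1.41 ± 0.10 on the log2 scale. Hoxb9 rose by 1.87 ± 0.23. Among genes with a mean of at least 5 CPM, the largest fall was that of Onecut3, a homeobox transcription factor, from 25.8 ± 4.54 to 1.95 ± 0.753 CPM (log2 fold change -3.72 ± 0.20). Igdcc3, a membrane protein of the immunoglobulin superfamily, fell from 331 ± 5.78 to 78.6 ± 3.27 CPM. Fignl2, a fidgetin-like ATPase, was lower by -1.89 ± 0.09 on the log2 scale, the secreted protein gene Wfdc1 by -2.53 ± 0.28, and the metabotropic glutamate receptor gene Grm2 by -1.61 ± 0.15. Aunip (-1.80 ± 0.23), whose product binds Aurora A, and the monooxygenase gene Moxd1 (-1.71 ± 0.23) completed the 10 with Lin28a, Hmga2 and Arid3b.

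Of 33 let-7 target genes, 23 fell and 2 rose (24 and 3 when adjusted over the list alone), with a median log2 fold change of -0.39. Hmga2 changed by -1.61 ± 0.05, the DNA-binding protein gene Arid3b by -1.48 ± 0.11 and the MAP kinase phosphatase gene Dusp9 by -1.47 ± 0.24. The list was lower than the other genes by the camera set test (adjusted p = 4.35e-15), and not with an estimated correlation between genes (adjusted p = 0.148). Erythroid markers were lower as well: 7 of 10 fell and none rose, the same counts when adjusted over the list alone (median -0.73; camera adjusted p = 3.19e-10, adjusted p = 0.148 with an estimated correlation). Among them, Alas2, the first enzyme of haem synthesis in red cells, fell from 38.2 ± 2.09 to 16.6 ± 1.57 CPM and the embryonic globin gene Hbb-bh1 changed by -1.10 ± 0.03 on the log2 scale.

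Of 50 ribosome biogenesis genes 34 fell and none rose (35 and 0 adjusted over the list alone; median -0.32; camera adjusted p = 2.38e-11, adjusted p = 0.148 with an estimated correlation). These included Ltv1 (-0.72 ± 0.12), which helps assemble the small subunit, Ftsj3 (-0.72 ± 0.14), a pre-rRNA methyltransferase, and Noc2l (-0.63 ± 0.10). Of 40 genes of the G1/S transition and DNA replication 26 fell and 1 rose (30 and 2 adjusted over the list alone; median -0.32; camera adjusted p = 3.19e-10, adjusted p = 0.148 with an estimated correlation). The replication licensing factor gene Cdc6 changed by -0.82 ± 0.16, the helicase subunit gene Mcm2 by -0.68 ± 0.08, Mcm10 by -0.74 ± 0.13 and the chromatin assembly factor gene Chaf1b by -0.75 ± 0.13. Of 40 genes of G2/M and mitosis 19 fell and 2 rose (21 and 2 adjusted over the list alone; median -0.14; camera adjusted p = 3.85e-05, adjusted p = 0.195 with an estimated correlation), among them the mitotic activator gene Cdc20 (-0.49 ± 0.09) and the kinase gene Aurka (-0.47 ± 0.08). Of 19 glycolysis genes 10 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.27; camera adjusted p = 0.00127, adjusted p = 0.301 with an estimated correlation), with Pkm at -0.53 ± 0.03, Ldha at -0.47 ± 0.03 and the glucose transporter gene Slc2a1 at -0.47 ± 0.05.

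The protein synthesis lists did not move as 1 group. Of 72 cytoplasmic ribosomal protein genes 23 rose and none fell, also when adjusted over the list alone (median 0.16; camera adjusted p = 3.09e-05, adjusted p = 0.195 with an estimated correlation), including Rpl39 (0.45 ± 0.05), Rplp0 (0.35 ± 0.03) and Rps20 (0.34 ± 0.03). Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. Of 43 translation factors 20 fell and 7 rose (21 and 8 adjusted over the list alone; median -0.15; camera adjusted p = 0.0159, adjusted p = 0.259 with an estimated correlation), with the initiation factor gene Eif3b at -0.65 ± 0.06 and Eif6, which keeps the ribosomal subunits apart, at -0.45 ± 0.08. Of 27 genes of endoplasmic reticulum chaperones and the unfolded protein response 10 fell and 2 rose (11 and 4 adjusted over the list alone; median -0.12; camera adjusted p = 0.00226, adjusted p = 0.227 with an estimated correlation), such as the chaperone gene Hspa5 (-0.42 ± 0.04) and the disulphide isomerase gene Pdia6 (-0.53 ± 0.05).

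Hox genes, which pattern the hindbrain and spinal cord along the body axis, were higher in dKO: 10 of 25 rose and 2 fell, also when adjusted over the list alone (median 0.19; camera adjusted p = 0.00198, adjusted p = 0.227 with an estimated correlation). Hoxb9 rose by 1.87 ± 0.23, Hoxa6 by 1.74 ± 0.44 and Hoxb8 by 1.15 ± 0.13. Of 23 nuclear and noncoding RNAs 10 rose and 3 fell, also when adjusted over the list alone (median 0.13; camera adjusted p = 0.0313, adjusted p = 0.275 with an estimated correlation). This call was lost after an adjustment for transcript GC content (adjusted p = 0.0722) and for length (adjusted p = 0.21), both added after the data were seen, and in the fit over all 8 libraries (adjusted p = 0.29). Mesenchyme and somite markers were lower, with 7 of 23 down and none up, also when adjusted over the list alone (median -0.19; camera adjusted p = 0.0345, adjusted p = 0.275 with an estimated correlation), among them the cartilage collagen gene Col2a1 (-0.82 ± 0.07). This call was lost without WT replicate 1 (adjusted p = 0.0522), WT replicate 2 (0.0508) or dKO replicate 1 (0.0659), and with the replicate number as a block (0.0531).

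**Figure D2:**
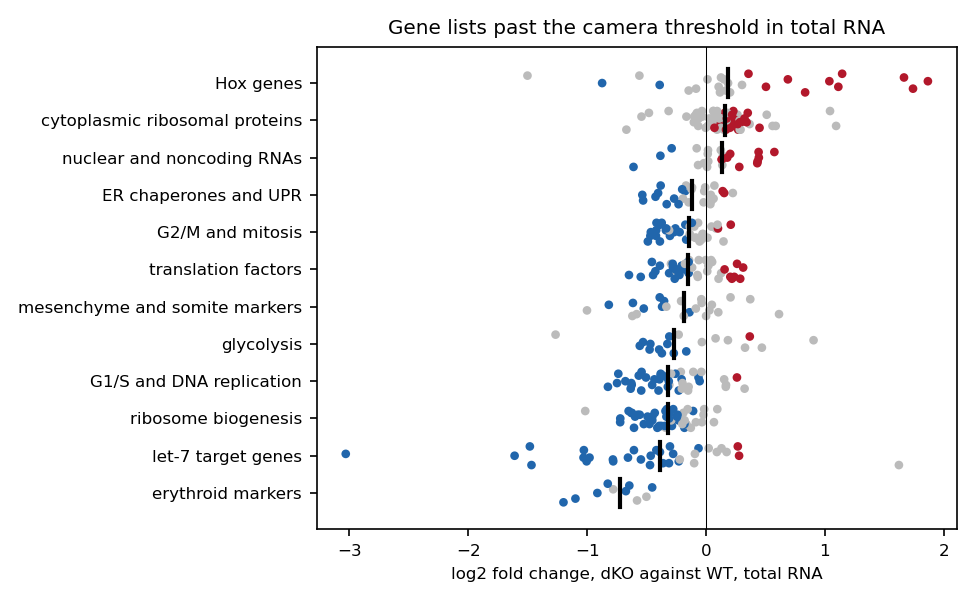
Log2 fold change of dKO against WT in total RNA for each tested member (points) of the 12 lists past the camera threshold, with the list median as a vertical bar. Red and blue points are genes past the adjusted p of 0.05 that were higher or lower in dKO, and grey points are the other members; the medians run from -0.73 for erythroid markers to 0.19 for Hox genes.

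Neural lists held members that moved both ways. Of 43 neuronal genes 17 rose and 9 fell (19 and 9 adjusted over the list alone; camera adjusted p = 0.0952), with the GABA-synthesising enzyme genes Gad1 (0.91 ± 0.15) and Gad2 (0.73 ± 0.07) up and the neurofilament gene Nefm (-1.30 ± 0.06) down. Of 34 neural progenitor genes 10 rose and 8 fell (11 and 10 adjusted over the list alone; camera adjusted p = 0.815), with the transcription factor gene Sox3 at -0.90 ± 0.08, Notch3 at -0.34 ± 0.04 and the glial glutamate transporter gene Slc1a3 at 0.58 ± 0.10. The list median of the progenitor genes was 0.01 while their mean was -0.02. Of 26 midbrain and hindbrain patterning genes 7 rose and 3 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.21), including Pax5 (0.92 ± 0.17) and Gbx2 (0.73 ± 0.11). Of 26 forebrain patterning genes 5 rose and 2 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.527), including Tcf7l2 (0.47 ± 0.04). Of 27 genes responding to Shh, Wnt and Notch signals 10 rose and 3 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.134).

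No call by camera was made for the remaining lists of signalling, stress and metabolism. Of 32 genes of the insulin, IGF and mTOR pathway 7 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.815), such as Irs1 (0.40 ± 0.05) and Igfbp5 (-0.36 ± 0.05). Of 33 integrated stress response genes 5 rose and 11 fell, also adjusted over the list alone (camera adjusted p = 0.0983), with the cystine transporter gene Slc7a11 up from 7.78 ± 1.63 to 17.8 ± 0.655 CPM and the alanyl-tRNA synthetase gene Aars at -0.70 ± 0.10. Of 30 p53 target genes 5 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.646, with the test upward and the median at -0.02). Cdkn1a, an inhibitor of the cell cycle, changed by 0.58 ± 0.13 and Pmaip1, a pro-apoptotic gene, by -0.87 ± 0.26, and neither call held without dKO replicate 2 (adjusted p = 0.124 and 0.0928). Of 18 immediate early genes 1 rose and 3 fell (camera adjusted p = 0.688). Of 73 nuclear genes of oxidative phosphorylation 8 rose and 17 fell (camera adjusted p = 0.373), such as the complex I subunit gene Ndufv1 (-0.72 ± 0.10). Of 75 mitochondrial ribosomal protein genes 3 rose and 15 fell (2 and 14 adjusted over the list alone; camera adjusted p = 0.0602), such as Mrps27 (-0.62 ± 0.13); this list passed with no filter on low counts (adjusted p = 0.0249).

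Among markers of other tissues, endothelial genes gave 1 rise and 1 fall in 14 (camera adjusted p = 0.86), neural crest genes 3 falls in 13 (0.21), epithelial genes 1 fall in 8 (0.646) and muscle and heart genes 1 fall in 6 (0.815). Of 13 macrophage genes 2 rose and 1 fell (0.646). The lysozyme gene Lyz2 changed by 1.27 ± 0.23, and without dKO replicate 1 it was at 0.64 and not called. C1qa, a complement gene, changed by -1.26 ± 0.38. It was not called without WT replicate 2 or dKO replicate 1, and was at -1.88 without dKO replicate 2. Of 5 sex-linked genes 3 rose and 1 fell. Xist, expressed from the inactive X chromosome of females, was lower in dKO (-0.61 ± 0.05) and the Y-linked gene Ddx3y was higher (0.53 ± 0.11), so the dKO and WT samples differed in their mix of sexes as measured by these genes. Every total RNA library held both, with Xist at 106 to 169 CPM and Ddx3y at 23.9 to 38.7 CPM, as a mix of male and female embryos would give. The mix was closer between replicates than between genotypes, so it is confounded with genotype. Transcripts encoded in the mitochondrial genome had no row in either table.

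The polysomal table was not a full transcriptome. Among genes with a mean of at least 100 counts, 2927 had a dKO to WT ratio of summed counts below -2.04 on the log2 scale and 2514 had one above -1.71, with none between. Of such genes in total RNA, 30.8% lay within 0.1 of the median ratio. The listed genes were thus picked for a difference between genotypes, and p-values and shares of changed genes among them are conditional on that choice. Scaling rests on the listed genes alone, without genes that did not change.

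The second comparison asked how the RNA on polysomes differed between genotypes among the listed genes. RNAs of let-7 targets, mitotic genes, ribosome biogenesis genes and red cell genes were lower in dKO polysomal RNA, and RNAs of Hox genes and of Shh, Wnt and Notch response genes were higher. These are calls by camera at a preset correlation. None of these lists passed with an estimated correlation (adjusted p from 0.465 to 0.49). That estimate was above the preset 0.01 only for the Shh, Wnt and Notch list (0.155) and the erythroid list (0.0584). The mitotic, ribosome biogenesis and Shh, Wnt and Notch lists also lost the call after the GC adjustment described here. The Hox rise was largest in members with few WT counts, and members with more counts moved both ways. Hmga2 was 5.57-fold lower and the mitotic cyclin gene Ccnb1 5.51-fold lower. Among genes with a mean of at least 5 CPM, the largest rises were those of Rn45s, the ribosomal RNA precursor, 69.9-fold, and of Lars2 and Mir6236, 66.8-fold and 235-fold. These sizes lean on dKO replicate 1: without it the log2 fold changes of Rn45s, Lars2 and Mir6236 were 5.43, 5.43 and 7.22, against 6.13, 6.06 and 7.88 with it. Of 5777 genes tested, 5760 passed, with 2728 higher and 3032 lower. The log2 fold change followed the GC content of the transcript over 5741 genes (Spearman rho = 0.764 across genes, which are not independent replicates). In total RNA the rho was -0.0872 over 14473 genes. These sets of genes are unlike, since only the polysomal genes were picked for a genotype difference. With each library adjusted for GC content, an alternative added after the data were seen, 2733 genes passed, with 1117 higher and 1616 lower; 2024 of the 5760 calls were kept with their direction, 702 were called in the opposite direction and 3034 were no longer called.

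**Figure D3:**
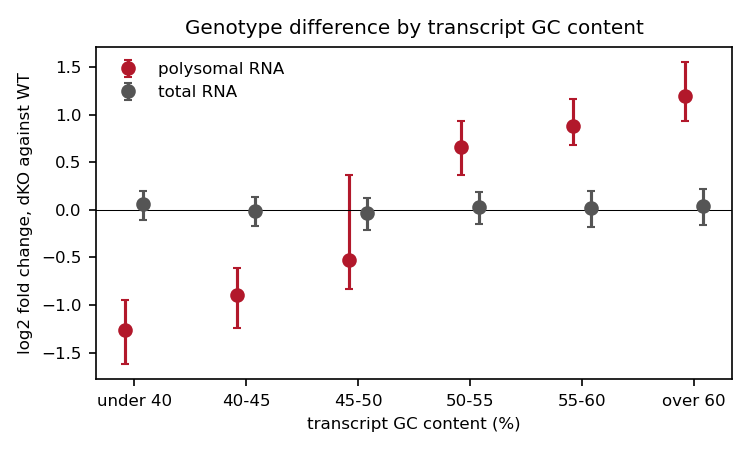
Median log2 fold change of dKO against WT by transcript GC content for genes in the polysomal table, in polysomal RNA (red) and in total RNA (grey), with bars from the lower to the upper quartile. The polysomal median runs from -1.26 under 40% GC to 1.19 over 60% GC, while the total RNA medians of these genes stay between -0.03 and 0.06.

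Rn45s took 9.52% and 4.58% of the counts of the listed genes in the dKO polysomal libraries, against 0.12% and 0.109% in WT. Its log2 fold change was 6.13 ± 0.42, that of Lars2 6.06 ± 0.39 and that of Mir6236 7.88 ± 0.50. The small nucleolar RNA genes Snord17 (3.31 ± 0.29) and Snord15a (3.11 ± 0.38) and the microRNA gene Mir320 (4.54 ± 0.78) were also among the 10 largest rises. These had Hox genes among them too, namely Hoxc10 (3.84 ± 0.39), Hoxc9 (3.68 ± 0.67) and Hoxa6 (3.31 ± 0.59), all with a WT mean near 1 CPM, and Neurod2 (3.20 ± 0.25). With 1 library left out the value ranged from 2.65 to 4.56 for Hoxa6, from 2.77 to 4.31 for Hoxc9 and from 3.57 to 5.25 for Mir320. Among the 10 largest falls by the same rule were Zxda, a zinc finger gene (-4.24 ± 0.34), Pigf, of glycolipid anchor synthesis (-4.16 ± 0.30), the noncoding Gt(ROSA)26Sor (-4.00 ± 0.35), the centromere protein gene Cenph (-3.87 ± 0.40), Onecut3 (-3.69 ± 0.41) and the complex I gene Ndufa12 (-3.46 ± 0.39). With 1 library left out Cenph ranged from -4.87 to -3.14 and Onecut3 from -4.73 to -2.94, and Gt(ROSA)26Sor reached -4.91. Anapc10, Snhg3 and Ankdd1b were also among them, and their dKO mean lay between 0.295 and 1.33 CPM. The GC adjustment moved Zxda to -5.96 and Onecut3 to -4.79, and Pigf to -3.49, Cenph to -3.15 and Gt(ROSA)26Sor to -2.79. Among the rises it moved Mir320 to 3.14, Hoxc9 to 2.85, Hoxa6 to 2.32 and Neurod2 to 2.12, and Snord15a to 3.52. All of these still passed.

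Of the 24 listed let-7 targets 18 fell and 5 rose, also when adjusted over the list alone (median -0.75; camera adjusted p = 0.00296, adjusted p = 0.465 with an estimated correlation), and after the GC adjustment the median was -0.34 (camera adjusted p = 0.000129, adjusted p = 0.708 with an estimated correlation). Hmga2 changed by -2.48 ± 0.07, Dusp9 by -1.61 ± 0.27 and Arid3b by -1.55 ± 0.13. Hmga1, a relative of Hmga2, was higher (1.51 ± 0.34) and lost its call after the GC adjustment (0.25; adjusted p = 0.516). Erythroid markers fell in 6 of 6 (median -1.32; camera adjusted p = 0.00483, adjusted p = 0.465 with an estimated correlation; GC-adjusted median -1.81), with Hbb-bh1 at -1.36 ± 0.07. Of 18 Hox genes 15 rose and 3 fell, also when adjusted over the list alone (median 2.81; camera adjusted p = 0.0183, adjusted p = 0.465 with an estimated correlation; GC-adjusted median 2.32). Most of these Hox genes had few WT counts, and Hoxd9, with none in WT and 15 and 8 in dKO, was at least 16-fold higher at a floor of 3 counts per library. Members with at least 100 counts in each WT library moved both ways. Hoxa5 (1.25), Hoxb2 (0.62), Hoxb6 (1.82) and Hoxb8 (1.14) rose, while Hoxa2 (-0.50), Hoxc4 (-0.86) and Hoxb1 (-2.42) fell. The large list median thus rests on members with few WT counts.

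The other polysomal lists that passed lost their call after the GC adjustment. Of 24 genes of G2/M and mitosis 23 fell and 1 rose (median -0.72; camera adjusted p = 0.00296, adjusted p = 0.465 with an estimated correlation; GC-adjusted median -0.20, adjusted p = 0.371). Ccnb1 changed by -2.46 ± 0.17 and the spindle gene Nusap1 by -2.19 ± 0.15, and both still passed after the adjustment (-1.77 and -1.31). Of 24 ribosome biogenesis genes 18 fell and 6 rose (median -0.75; camera adjusted p = 0.0341, adjusted p = 0.465 with an estimated correlation; GC-adjusted median -0.38, adjusted p = 0.108), including Nop10 (-2.44 ± 0.12) and the nucleolar chaperone gene Npm1 (-1.61 ± 0.07). The call for this list was also lost with RLE scaling (adjusted p = 0.0543) and without any 1 of the 4 libraries. Of 14 Shh, Wnt and Notch response genes 13 rose and 1 fell (median 0.79; camera adjusted p = 0.0274, adjusted p = 0.49 with an estimated correlation; GC-adjusted median 0.01, adjusted p = 0.648), such as Sp5 (1.84 ± 0.17) and Wnt1 (1.64 ± 0.24); after the adjustment Sp5 was at 0.54 and Wnt1 no longer passed (0.43; adjusted p = 0.137). These counts were the same when adjusted over each list alone. Nearly every listed gene was called, and 47.3% of the listed genes outside the ribosome biogenesis list were higher, so a count of falls has to be read against that share. By Fisher's exact test of direction against the other listed genes, a check added after the data were seen, mitotic genes (adjusted p = 0.000117), Shh, Wnt and Notch response genes (0.00667), Hox genes (0.0185) and immediate early genes (0.0185) differed, while let-7 targets (0.0569), ribosome biogenesis genes (0.127) and erythroid markers (0.125) did not pass. That test also treats genes as independent and takes no account of GC content or of low counts, such as those of most Hox members.

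Lists with no call by camera in polysomal RNA before the GC adjustment included the cytoplasmic ribosomal proteins, of which 20 rose and 11 fell (median 0.66, mean -0.10; camera adjusted p = 0.0808), and after the GC adjustment their median was -0.04. Rpl39 (-2.56 ± 0.14) and Rps6 (-2.17 ± 0.27) were among those that fell. Neural progenitor genes gave 17 rises and 8 falls (median 0.44; camera adjusted p = 0.0808), with Id1 at 1.42 ± 0.12, Hes6 at 1.41 ± 0.12 and Notch3 at 1.32 ± 0.12. After the GC adjustment 5 were higher and 8 lower (median 0.00) and Id1 was at 0.60, while Hes6 (0.13; adjusted p = 0.144) and Notch3 (0.18; adjusted p = 0.0906) no longer passed. Neuronal genes gave 10 rises and 10 falls in 21 (camera adjusted p = 0.988), with Nefm at -1.65 ± 0.13. All 8 listed immediate early genes rose (median 1.25; camera adjusted p = 0.0808; GC-adjusted median 0.50), among them Junb (2.61 ± 0.48, and 1.80 without dKO replicate 1) and Nr4a1 (2.02 ± 0.26). Glycolysis genes fell in 5 of 6 (camera adjusted p = 0.633) and passed after the GC adjustment (median -0.85; camera adjusted p = 0.0271, adjusted p = 0.749 with an estimated correlation). Of these Pgk1 changed by -1.81 ± 0.28 (-2.41 without dKO replicate 2), while Pkm was higher (0.68 ± 0.06) and turned lower after the GC adjustment (-0.34; adjusted p = 0.00153). Of 10 mesenchyme genes 6 rose and 4 fell (camera adjusted p = 0.298), with the collagen gene Col1a1 at 2.26 ± 0.11. Xist changed by -2.42 ± 0.18 and Ddx3y by -1.54 ± 0.21, the latter not past the threshold after the GC adjustment (adjusted p = 0.425). RLE scaling moved the median of all listed genes from -0.35 to -0.11 and gave 2729 higher and 2396 lower genes, so the balance of rises and falls depends on the scaling.

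The third comparison asked which of the listed RNAs were enriched on or depleted from polysomes in WT tissue, relative to total RNA. Of 11 listed nuclear and noncoding RNAs 7 were depleted and 4 were not called. Rpph1, the RNA of ribonuclease P, was 6.61-fold lower in polysomal than in total RNA, the imprinted noncoding RNA H19 5.51-fold lower, and Terc, the telomerase RNA, 3.56-fold lower. The messenger RNA of embryonic globin Hbb-bh1 was 1.47-fold higher. Of 41 oxidative phosphorylation genes 8 were called higher, and their call as a list was lost with an estimated correlation (adjusted p = 0.156). Of 5780 genes tested, 201 were higher and 492 lower in polysomal RNA. The log2 fold change was -2.73 ± 0.08 for Rpph1, -2.78 ± 0.07 for the near-identical Rprl3, whose reads cannot be told from those of Rpph1 with certainty, -2.46 ± 0.04 for H19, -1.83 ± 0.08 for Terc and -1.64 ± 0.10 for the adaptor protein gene Ap3s1. Among called genes with a mean of at least 5 CPM, the largest rises were those of Snapc5 (0.65 ± 0.17), Hbb-bh1 (0.55 ± 0.05), the histone genes Hist2h2bb (0.54 ± 0.03) and Hist1h2bb (0.53 ± 0.05), and the spliceosome gene Snrpd3 (0.53 ± 0.07). The call for Snapc5 was lost when any 1 of the WT or total RNA libraries was left out. Histone genes share sequence between copies, so their counts are uncertain.

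Of 11 nuclear and noncoding RNAs 7 were lower in WT polysomal RNA and none higher (median -0.60, camera adjusted p = 2.77e-41, adjusted p = 0.00305 with an estimated correlation). The largest log2 fold change among them was 0.129. Unscaled counts of Xist were 2541 and 2551 in WT total and 3663 and 4101 in WT polysomal RNA. Those of H19 were 17950 and 17694, and 4904 and 5137, so the nuclear RNA Xist was not depleted as H19 was. These counts are not on a common scale, since the polysomal sums cover the listed genes only. On the scale of the fit H19 was 5.51-fold lower, and the raw counts do not show a rise of Xist. Of 31 cytoplasmic ribosomal protein genes 11 were lower (14 adjusted over the list alone; median -0.16; camera adjusted p = 0.000159, adjusted p = 0.0673 with an estimated correlation), with Rplp1 at -0.65 ± 0.05. Of 19 insulin, IGF and mTOR pathway genes 5 were lower (camera adjusted p = 2.0e-08, adjusted p = 0.0323 with an estimated correlation), led by H19, which is noncoding, and Igf2 (-0.73 ± 0.04). The oxidative phosphorylation list, with 1 member lower, had a median of 0.17 (camera adjusted p = 4.28e-05, adjusted p = 0.156 with an estimated correlation), with Ndufa4 at 0.47 ± 0.08. Erythroid markers (3 higher and 1 lower of 6; camera adjusted p = 0.00532, adjusted p = 0.192 with an estimated correlation) and mitochondrial ribosomal proteins (1 higher and 1 lower of 42; camera adjusted p = 0.0426, adjusted p = 0.181 with an estimated correlation) also passed, the latter not without WT total replicate 1, WT polysomal replicate 1 or either dKO polysomal replicate. Leaving out either dKO polysomal library, which narrows the shared spread, raised the count of called genes to 1986 or 1998, and leaving out any 1 other library gave between 179 and 416.

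The fourth comparison asked whether the genotype difference in polysomal RNA differed from that in total RNA, as an interaction over all 8 libraries. Relative to total RNA, Rn45s was 137-fold and Lars2 94.0-fold more abundant in dKO than in WT polysomal RNA, and Ccnb1 was 5.50-fold less abundant. The rise of Lars2 was not shown to be separate from that of Rn45s. Nes and Notch3, which encode an intermediate filament and a receptor of neural progenitors, were 2.68-fold and 3.25-fold more abundant (1.42 and 1.70 on the log2 scale); after the GC adjustment the log2 values were 0.55 and 0.57. Of 5780 genes tested, 2524 were higher and 2647 lower. The interaction was 7.10 ± 0.40 on the log2 scale for Rn45s, 6.55 ± 0.40 for Lars2, 8.06 ± 0.66 for Mir6236 and 3.54 ± 0.54 for Snord15a. Without dKO polysomal replicate 1 the first 3 were at 6.42, 5.94 and 7.43. The histone gene Hist1h2bp (3.63 ± 0.89) was also among the 10 largest rises, but WT total replicate 1 carried much of it, and without that library the value was 1.78. Other genes among them were Snord17 (2.99 ± 0.39), the phosphatase gene Dusp5 (2.93 ± 0.48) and the small nuclear RNA Rnu11 (2.90 ± 0.33). After the GC adjustment Snord17 was at 2.54, Dusp5 at 1.98 and Rnu11 at 2.375. By the rule for named genes the largest falls included Pigf (-4.25 ± 0.30), Gt(ROSA)26Sor (-4.17 ± 0.33), Zxda (-4.12 ± 0.36) and Anapc10 (-4.09 ± 0.48). With the GC adjustment Pigf was at -3.62, Gt(ROSA)26Sor at -2.91, Zxda at -5.79 and Anapc10 at -3.01. Without dKO polysomal replicate 2 Gt(ROSA)26Sor was at -5.07 and Anapc10 at -6.42. No gene list passed by camera; mitotic genes (1 higher and 19 lower of 24) and neural progenitor genes (16 higher and 6 lower of 25) were closest, each at an adjusted p of 0.0626. After the GC adjustment 4 mitotic genes were higher and 5 lower (median 0.10; camera adjusted p = 0.977), and 8 progenitor genes were higher and 9 lower (median -0.05; camera adjusted p = 0.993). The let-7 target list had 5 members higher and 10 lower (median -0.12, camera adjusted p = 0.494). After the GC adjustment 7 of its members were higher and 10 lower (median 0.007, camera adjusted p = 0.977). For the targeted genes the interaction was 0.69 ± 0.19 for Lin28a and -0.74 ± 0.17 for Lin28b. The GC adjustment left 2373 genes past the threshold, with 993 higher and 1380 lower; Lin28a then no longer passed (0.48; adjusted p = 0.0682), and Lin28b turned positive and did not pass (0.24; adjusted p = 0.32).

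Across 5737 genes tested in both assays, the polysomal and the total RNA log2 fold changes between genotypes had a Pearson r of 0.249 and a Spearman rho of 0.196, and 56.2% had the same sign. Genes are not independent replicates, so no p-value is given. Of 2413 genes called in both assays, 691 were higher in both, 777 lower in both, 525 higher in total and lower in polysomal RNA, and 420 the reverse.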

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

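Chosen after the result was seen were the GC and length adjustments, the test of whether polysomal changes were already present in total RNA, the use of the length adjustment to weigh length, and the need for the upper confidence bound of the odds ratio near the targeted loci to lie under 1.2, which left that outcome as it was. The bounds of the other tests were written before the values they measure were seen, but after first fits of both tables had shown the patterns.

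The genotype difference differed between polysomal and total RNA for 5171 of 5780 genes by the interaction test. Because the polysomal table lists genes picked for a genotype difference, this count does not describe the transcriptome. Among the genes named in the report, whose printed subset was picked after values were seen, 16 were past the threshold in both RNA fractions with opposite signs and past it in the interaction. Lower in total and higher in polysomal RNA were Eif6 (interaction 1.28), Noc2l (1.17), Pkm (1.24), Notch3 (1.70), Nes (1.42), Col2a1 (2.29), Aars (1.23), Ndufv1 (1.30), H19 (0.67), Hist1h2bp (3.63), Rn45s (7.10) and Lars2 (6.55). Higher in total and lower in polysomal RNA were Rpl39 (-2.96), Rps20 (-1.32), Ap3s1 (-1.70) and Ddx3y (-2.04). The opposite signs of Hist1h2bp rest on WT total replicate 1, which had 18.9 CPM against 3.04 in WT replicate 2 and 3.37 and 2.90 in dKO; the interaction without that library was 1.78. The GC adjustment, chosen after the data were seen, brought most of these interactions closer to 0: Eif6 to 0.27, Pkm to 0.24, Ndufv1 to 0.36, Nes to 0.55, Notch3 to 0.57, Col2a1 to 1.01, Rps20 to -0.39, Ap3s1 to -0.75 and Ddx3y to -0.68. It left Lars2 at 6.17, Hist1h2bp at 3.06 and Rpl39 at -2.93, while Rn45s has no GC value and could not be moved by it. The polysomal change of Pkm turned to -0.34, the sign it had in total RNA, and those of Notch3 (0.18; adjusted p = 0.0906) and Ddx3y (-0.25; adjusted p = 0.425) no longer passed. The interaction of H19 changed sign (-0.22; adjusted p = 0.00505), and Noc2l (0.27; adjusted p = 0.144) and Aars (0.31; adjusted p = 0.151) were no longer called.

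The polysomal genotype difference rose with transcript GC content (Spearman rho = 0.764), which goes with a GC bias in these libraries, and the dKO polysomal replicates also differed from each other along GC content (rho = 0.337, against 0.00361 in WT). Against a change already present in total RNA as the whole cause stands the correlation of the log2 fold changes (r = 0.249), and against transcript length the rho of 0.16 after the GC adjustment, which the bounds written before that value was seen left undecided, with 5619 of 5760 calls kept in direction after a length adjustment. Translation that selects coding messages by GC content remains open: rho was 0.539 among 142 noncoding genes (bootstrap interval 0.40 to 0.657) and 0.772 among coding genes, between the bounds written before these values were seen. For the let-7 targets a GC trend alone does not account for the polysomal fall, since their median moved from -0.75 to -0.34 with the adjustment, with 13 then lower and 2 higher and a camera adjusted p of 0.000129 (0.708 with an estimated correlation). That adjusted median is near the list's total RNA median of -0.39. The GC-adjusted interaction of the list had a median of 0.007 (camera adjusted p = 0.977). As a list, a polysomal fall beyond that in total RNA was thus not shown. A GC bias may thus account for much of the polysomal difference, and how the dKO fractions were collected, the selection of the listed genes and the scaling without unchanged genes are not separated from genotype here.

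The Hox genes were higher in dKO total RNA (median 0.19, camera adjusted p = 0.00198, adjusted p = 0.227 with an estimated correlation). A GC trend does not account for this, as the median after the adjustment was 0.21. More caudal tissue in the dKO samples could raise Hox genes, and 15 other genes of caudal neural tissue, listed after the Hox rise but before their own values were seen, had a median of -0.0023 and were not called as a list by camera, with Lbx1 (0.50) and Pax2 (0.39) higher and Nkx1-2 (-2.09) lower. Not all of the 15 mark caudal tissue alone: Pax2 and Lmx1b are also in the midbrain and hindbrain list, and Isl1 is in the neuronal list. Their flat median thus weighs little on dissection. The bound, written after the Hox rise, also needed a Hox median over 0.3, so dissection and an effect of genotype on Hox genes cannot be told apart for this list.

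Genes near the targeted loci might differ through strain variants carried with the knockout alleles. Within 10 Mb of Lin28a and Lin28b, 91 of 313 tested genes were called in total RNA (29.1%), against 4364 of 14158 elsewhere (30.8%), an odds ratio of 0.92 (interval 0.711 to 1.18; one-sided Fisher p = 0.765). A raised share of changed genes there is thus not seen, while a variant in a single gene is not excluded.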

How the results depend on the processing

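Added after the data were seen were the GC-adjusted, length-adjusted and gap-centred settings and the fits without Rn45s, Lars2 and Mir6236. Where no cause is given, the cause was not tested.

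In total RNA (4485 genes) the count moved to 2944 with DESeq2, to 1286 in the fit over all 8 libraries, which tests fewer genes, and to 226 with a log2 fold change of at least 1. Leaving out 1 library gave 3188 to 3492. Of the 12 lists past camera, 0 passed with an estimated correlation. By fry, which tests each list without reference to other genes, all 12 passed, with the largest adjusted p at 0.0419 for glycolysis genes. Lists not past camera also passed by fry, such as mitochondrial ribosomal proteins (adjusted p = 0.0223) and neural crest markers (0.043).

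For genes changed in dKO against WT, polysomal RNA (5760), the GC adjustment gave 2733 and a log2 fold change of at least 1 gave 2360, and leaving out 1 library 4708 to 5763. Of 23 lists, 6 passed by camera, 0 with an estimated correlation and 20 by fry, which tests each list without reference to other genes. Pkm reversed to -0.34 after the GC adjustment.

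For WT polysomal against total RNA (693 genes) limma-voom gave 1177 and a log2 fold change of at least 1 gave 24. Leaving out 1 library gave 179 to 1998, with the high values of 1986 and 1998 when a dKO polysomal library was left out. Of the 6 lists past camera, 2 passed with an estimated correlation, and fry called 12.

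For genes with changed polysome association in dKO (5171, the interaction) the GC adjustment gave 2373 and a log2 fold change of at least 1 gave 2219, and leaving out 1 library 4818 to 5310. Lin28b reversed to 0.24 after the GC adjustment. No list passed by camera, 18 passed by fry, and leaving out 1 library gave 0 to 1.

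The correlation of log2 fold changes (0.249) was 0.201 for genes with a mean of at least 20 CPM, 0.296 after the GC adjustment and 0.198 to 0.266 with 1 library left out. With replicate number as a block the counts were 4369, 5771, 598 and 5128. Deviations of like-numbered replicates correlated at -0.0148 to 0.0361, so no sign of pairing was seen. Replicates that differ only by technical noise would not correlate even if paired, so pairing is not excluded.

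Over the named genes and the settings tried, comparisons that kept their side of the threshold were counted. They were 902 in total RNA, 724 in polysomal RNA, 186 in WT polysomal against total RNA and 394 in the interaction. Direction had to hold only where the main or the other setting made a call. A further 7, 5, 9 and 1 kept direction and lost the call. For the lists, 329, 305, 295 and 389 kept their side under the same rule, 10, 8, 4 and 0 lost the call and 1, 9, 0 and 2 gained it. Those kept include lists called in neither setting whose median changed sign. The cytoplasmic ribosomal proteins in polysomal RNA moved from 0.66 to -0.04 with the GC adjustment in this way.

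Where a group was left with 1 library, that library is assumed to vary like the others. Polysomal depth is not known from the listed genes, and low dKO counts limit the size of the largest falls.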

Other observations

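Chosen after their values were seen were the genes named here. Nfia (log2 fold change 1.02 ± 0.05) and Nfib (0.94), which with Nfix belong to the nuclear factor I family, were higher in dKO total RNA. Igf2bp1, an RNA-binding protein gene in the let-7 target list, was lower in total (-1.03) and polysomal RNA (-1.05). The retinoic acid binding protein genes Crabp1 (-0.91 and -0.87) and Crabp2 (-1.10 and -0.67) were lower in both. Of the Y-linked genes, Eif2s3y (0.67) and Kdm5d (0.42) were higher in dKO total RNA, while Uty (0.14) was not past the threshold. Between the dKO polysomal replicates the count ratio was 0.672 for the median listed gene and 1.5 for Rn45s, 1.40 for Lars2 and 1.43 for Mir6236.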
